A study of Mus musculus with 41 samples.

How the data were processed

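The series holds 41 RNA-seq libraries in 15 groups, made from mouse intestinal cells sorted by flow cytometry at embryonic days 11.5 (E11.5) and 13.5 (E13.5) and in adults. Per the labels, each library started from 250 sorted cells of mixed C57BL/6 and CD1 background, single embryos at E11.5 and pools of 6 to 12 embryos at E13.5. Poly(A) RNA was reverse transcribed and amplified over 15 cycles with a SMARTer kit, the cDNA was sheared, libraries were made with a NuGEN Ovation Ultralow kit, and single-end reads of 50 bp were sequenced. The deposited files hold raw gene counts, 1 value for each of 23366 gene symbols plus 5 category totals. The authors list bcl2fastq 1.8.4, STAR 2.3.1z13, SAMtools 1.2, HTSeq 0.6.1p1 and DESeq2 1.6.3 with the mouse assembly mm9, without stating the role of each tool, the annotation, the strand setting or any read filter. All values in the files were whole numbers, as counts must be. No reads were available, so alignment and counting were not repeated, and reads shared between a gene and its pseudogenes or paralogs were not resolved.

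The category totals were kept out of library sizes and tests. Gene counts per library, in mega-counts (M), were 31.7 to 38.9 M at E11.5, 30.0 to 51.2 M at E13.5, 28.2 to 31.1 M in the adult stem cell group and 13.6 to 20.3 M in the adult segments. Reads without a gene, as a percentage of all counted reads, were 12.0 to 22.1, 22.2 to 28.7, 23.2 to 31.0 and 7.1 to 9.3 in the same order. Reads aligned to several places made up 17.6 to 22.3, 22.1 to 26.2, 25.4 to 30.4 and 12.0 to 15.4%. All 40 pairs of replicates within a group were checked for copied files: 0 were identical, and the scatter between replicates, as chi-square per degree of freedom, was 23.7 to 238, well above that of a repeated read-out of the same library.

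Tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Genes passed filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and quasi-likelihood F tests with robust dispersion were adjusted over all tested genes by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05. The E11.5 EpCAM+ and Lgr5+ groups were fitted together, as were the 7 groups of adult segments; the E11.5 comparisons of epithelium with mesenchyme used a fit of those 4 groups, and other comparisons used the compared groups alone. Levels are counts per M (CPM) after TMM scaling in that fit, and plain CPM in the figures, in the opening paragraph of the report, for values of single libraries and where so stated, except in the search for libraries standing apart. A value after ± is the standard error of a log2 fold change or the standard deviation of a CPM mean. Where all libraries of a group were at 0, a fold is a lower bound. It divides the mean of the other group by a floor of 3 counts per library. Such bounds cover counting at that floor and not replicate scatter. Standard errors cover counting and replicate scatter only. A set of 16 comparisons and 3 overlaps between them was fixed before the data were examined, with 38 gene lists written from general knowledge of gut regions, epithelial cell types, signalling pathways and other cell types.

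Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01 and adjusted over all lists of a comparison. The same test with a correlation estimated from the residuals is printed as "with an estimated correlation", and fry was run as another test. Members were also adjusted over the list alone. Genes were named by a rule: Id2 and Lgr5 everywhere, the 8 largest rises and 8 largest falls among called genes with a group mean of at least 5 CPM and no overlap between the groups, and up to 4 members of each list by smallest p; unnamed gene models were left out and the overlap condition was not used for interaction terms. Overlaps of called genes used Fisher's exact test against the product of both counts over the genes tested in both. That test treats genes as independent, so its p does not measure spread between libraries. Where both comparisons used the same controls, simulated counts with shared controls gave the correlation that replicate scatter in those controls creates.

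Alternatives for each comparison were RLE size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a block, the compared groups alone, and each library left out in turn. With at least 3 pairs, same-numbered libraries were treated as pairs if the correlation of deviations from the group means was over 0.1 for every pair, decided before the calls were compared. The Id2KO Lgr5+ and EpCAM+ libraries at E11.5 met this rule (0.13, 0.21 and 0.11; other pairs -0.12 to -0.02), so values with the block are given where it changed a call or moved a count by over 1.5 times. Further alternatives were added after the results were seen: leaving out 3 libraries with over 100 CPM of C1qa, the level of Hbb-y as a covariate, the mean of the Id2KO EpCAM+ and Lgr5+ groups, means over the middle and posterior segments, and fits without the wild-type middle and posterior libraries.

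The procedure was tested on simulated data with the group sizes and library sizes of these libraries. Dispersions followed their trend over mean level, and 200 genes and a list of 20 were changed by 2-fold or 4-fold. Of the genes changed 2-fold, 25.5% were called for the E11.5 EpCAM+ genotype comparison, 39.2% for E13.5 Lgr5+ against EpCAM+ and 37.8% for the adult posterior genotype comparison; of those changed 4-fold, 64.3, 74.7 and 77.3%. For the interaction at E11.5 the shares were 5.2 and 38.8%. Unchanged genes made up at most 6.5% of the calls, the changed list was called in all simulations, and 0 of 20 unchanged lists were called. Genes were simulated independently of each other, so these list counts do not cover lists whose members vary together. Genes that vary more than the trend were not simulated, so the shares of calls do not cover them. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Results for some genes are not reported here.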

Results

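The data comprised 41 libraries: E11.5 EpCAM+ epithelium and EpCAM- mesenchyme from wild-type and Id2KO embryos (n = 3 per group), Lgr5+ cells of Id2KO embryos (n = 3), and E13.5 Lgr5+ and EpCAM+ cells (n = 4 each). Adults gave Lgr5+ stem cells (n = 4) and further Lgr5+ cells from anterior, middle and posterior intestine labelled wild-type or Id2KO (n = 2 per group). A Tomato+ posterior Id2KO group (n = 2) completed the series. Libraries held 13.6 to 51.2 M gene counts and 13407 to 18144 detected genes. Id2, an inhibitor of basic helix-loop-helix transcription factors, averaged 5961 CPM in E11.5 wild-type EpCAM+ cells, 3171 in E13.5 EpCAM+ cells and 307 in adult stem cells. Sex differed between groups: the Y-linked Ddx3y was at 0 CPM in all adult segment libraries and at 167 to 236 in the adult stem cell group. The E11.5 wild-type EpCAM+ libraries, labelled as single embryos, held both Ddx3y (18.0 to 25.8 CPM) and Xist (251 to 575), the X-inactivation RNA of female cells, whereas each Id2KO library was rich in either Xist or Ddx3y. Genotype and sex mix therefore differed together at E11.5.

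What loss of Id2 changed in the embryonic epithelium was addressed by E11.5 Id2KO against wild-type EpCAM+ cells (n = 3 each). Id2 was 160, 159 and 182 CPM in the Id2KO libraries and 5308 to 6600 in wild-type libraries, a fall of -5.12 ± 0.19 (adjusted p = 1.5e-07). Wild-type epithelium held almost no Smoc2, a secreted calcium-binding protein of adult crypt base stem cells. In Id2KO cells Smoc2 rose by 7.80 ± 0.30 (259 ± 66.8 against 1.15 ± 0.405 CPM, adjusted p = 1.5e-07). Lgr5, the receptor that marks the stem cells themselves, did not pass (-0.32 ± 0.46, adjusted p = 0.84; 5.78 ± 2.98 against 7.23 ± 3.55 CPM). In all, 132 genes were higher and 119 lower of 15153 tested, and 1947 genes had an unadjusted p under 0.05.

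Of the BMP pathway, Id3, a BMP target and relative of Id2, rose by 2.25 ± 0.18 (1344 ± 239 against 282 ± 56.2 CPM, adjusted p = 6.2e-05). The ligand gene Bmp7 rose by 1.84 ± 0.17 (52.7 ± 3.87 against 14.7 ± 1.98 CPM, adjusted p = 0.00025). Sfrp5, a secreted Wnt inhibitor of the foregut, rose by 2.35 ± 0.17 (972 ± 175 against 191 ± 20.3 CPM). Osr2, a zinc finger factor placed in the distal small intestine list, fell by 3.25 on the log2 scale (25.2 ± 11.7 against 240 ± 3.27 CPM, adjusted p = 0.00016). Esr1 rose by 4.25 ± 0.27 (107 ± 22.5 against 5.59 ± 0.869 CPM). Its ligand-binding domain is also part of CreERT2 constructs. The labels do not name the Id2 allele, so receptor and construct were not told apart. Rpl29, a ribosomal protein gene with many pseudogenes, fell by 6.07 on the log2 scale (0.968 ± 0.0641 against 65.1 ± 11.7 CPM).

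Among the lists, 10 of 38 passed at the preset correlation and 1 of these still passed with an estimated correlation, the distal small intestine list. It had 0 members higher, 2 lower (Osr2 and Bex4) and 6 not passing of 8 tested. Adjusted over the list alone, 1 was higher and 4 were lower (adjusted p = 1.9e-08, and adjusted p = 0.028 with an estimated correlation). Cell cycle genes shifted upward, with 6 of 28 higher, 0 lower and 22 not passing, and 13 higher over the list alone (adjusted p = 2.5e-10, but adjusted p = 0.16 with an estimated correlation). Top2a, the topoisomerase of dividing cells, rose by 0.88 ± 0.16. BMP signalling had 3 higher, 0 lower and 11 not passing of 14, with 4 and 1 over the list alone (adjusted p = 0.0021, but adjusted p = 0.16 with an estimated correlation). Endoderm and epithelium had 7 higher, 0 lower and 19 not passing of 26, with 8 and 1 over the list alone (adjusted p = 0.0012, but adjusted p = 0.18 with an estimated correlation). Mesenchyme genes moved the other way, with 0 higher, 1 lower and 15 not passing of 16 (adjusted p = 0.0021, but adjusted p = 0.4 with an estimated correlation). Vim, an intermediate filament gene of that list, was 60.5, 143 and 43.1 CPM in Id2KO and 207, 192 and 180 CPM in wild-type libraries. The wild-type EpCAM+ libraries thus carried more of this transcript. Vim does not measure mesenchyme alone, being at 571 to 688 CPM in Id2KO Lgr5+ and 215 to 430 CPM in mesenchyme libraries. The stem cell list was not called (adjusted p = 0.094): Smoc2 and Sox9 were higher, Tnfrsf19 lower and 25 of 28 did not pass. Leaving out Id2KO replicate 3 gave 162 called genes, and leaving out wild-type replicates 1, 2 or 3 gave 118, 75 and 99, against 251. Bex4 (-1.04 ± 0.17) lost its call without wild-type replicate 2 (-1.05, adjusted p = 0.057) or 3 (-0.92, adjusted p = 0.055).

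**Figure D1:**
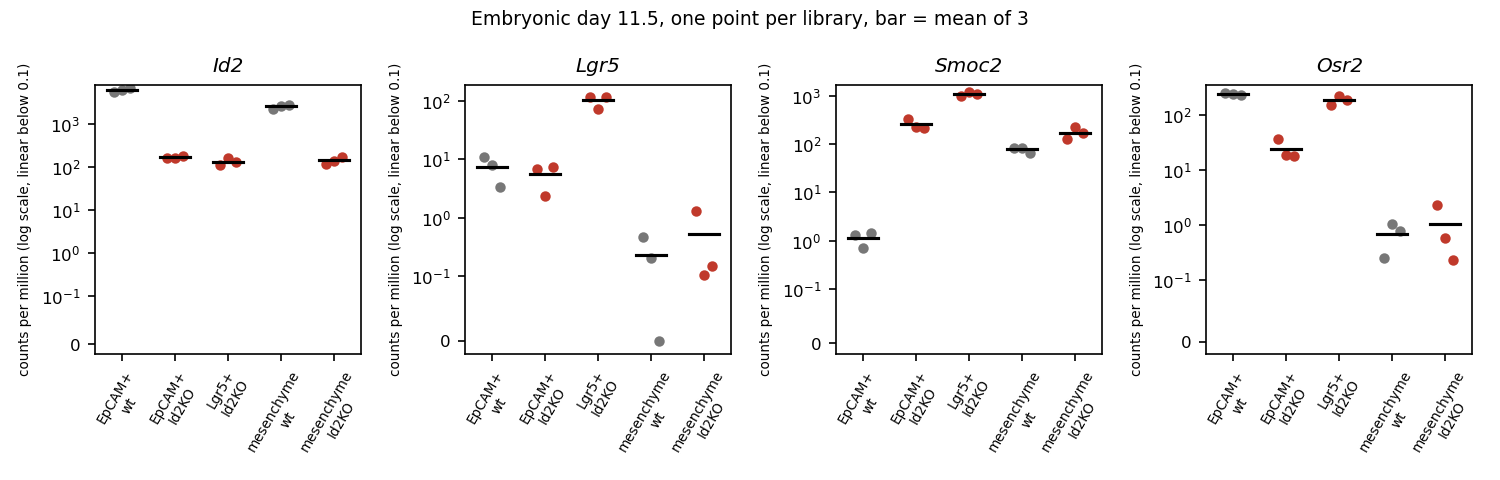
Id2, Lgr5, Smoc2 and Osr2 in the 5 E11.5 groups, in plain CPM on a log scale that is linear below 0.1; each point is a library (n = 3) and each bar a group mean. Mean Smoc2 was 1.16 CPM in wild-type EpCAM+, 253 in Id2KO EpCAM+ and 1075 in Id2KO Lgr5+ cells.

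The same genotype comparison in mesenchyme (n = 3 each) asked whether the change was specific to epithelium. Id2 fell by 4.52 on the log2 scale (125 ± 25.7 against 2866 ± 300 CPM, adjusted p = 1.9e-06). Red cell transcripts dominated the difference. Hbb-y, the embryonic beta-globin, held 15.7, 14.0 and 12.6% of counts in wild-type and 3.0, 1.3 and 3.6% in Id2KO libraries. Esr1 rose by 8.83 ± 0.41 (103 ± 24.8 against 0.225 ± 0.12 CPM), with the reservation given for the epithelium, and Rpl29 fell by 5.81 on the log2 scale. In all, 4 genes were higher and 117 lower of 13734 tested, with 979 at an unadjusted p under 0.05. Of 36 lists 4 passed, and the erythroid list alone still passed with an estimated correlation: 8 of 8 members were lower (adjusted p = 4.4e-83, and adjusted p = 0.026 with an estimated correlation). Hbb-y separated the genotypes completely, so smaller changes could not be parted from red cell content. The changes of Id2, Esr1 and Rpl29 were also present in EpCAM+ cells, where Hbb-y was only 50.3 to 65.2 CPM in Id2KO and 77.8 to 96.8 CPM in wild-type libraries, so red cell content did not account for these. Leaving out wild-type replicate 1 or 2 gave 67 and 76 genes.

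Whether the genotype effect differed between epithelium and mesenchyme was tested as an interaction (n = 3 in each of 4 groups). The effect on Smoc2 was larger in EpCAM+ cells by 7.02 ± 0.40 (adjusted p = 1.9e-06), because mesenchyme expressed Smoc2 with Id2 (94.7 CPM) and without it (162 CPM). Id3 (2.25 ± 0.25, adjusted p = 0.00082) and Sfrp5 (2.91 ± 0.33, adjusted p = 0.00082) also had positive terms, while Wnt5a, a ligand of the non-canonical pathway, had a negative one (-2.45 ± 0.33, adjusted p = 0.0035). The term for Id2 itself did not pass (-0.61 ± 0.24, adjusted p = 0.48). Interaction terms were positive for 66 genes and negative for 27 of 15680 tested, with 1277 at an unadjusted p under 0.05. Of 38 lists 10 passed and 3 still did with an estimated correlation. These were erythroid (5 higher, 0 lower, 3 not passing of 8; 7 and 0 over the list alone; adjusted p = 8.3e-20, and adjusted p = 0.018 with an estimated correlation) and mesenchyme (0 higher, 2 lower, 16 not passing of 18; 0 and 4 over the list alone; adjusted p = 0.033 with an estimated correlation). The last was posterior Hox (0 higher, 0 lower, 12 not passing of 12; 0 and 4 over the list alone; adjusted p = 0.03 with an estimated correlation). Dcn, a collagen-binding proteoglycan, is an example from the mesenchyme list (-3.90 ± 0.63). It was at 6.08 CPM in wild-type and 0.366 in Id2KO EpCAM+ cells, beside 186 and 171 CPM in mesenchyme. Whether the other members followed this pattern was not tested. Leaving out Id2KO EpCAM+ replicate 2 gave 142 genes.

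Wild-type EpCAM+ cells against mesenchyme (n = 3 each) gave the scale of a difference between tissues. Id2 was higher in epithelium by 0.82 ± 0.17 (5464 ± 810 against 3093 ± 320 CPM, adjusted p = 0.0031). Shh, the hedgehog ligand that gut epithelium sends to mesenchyme, was higher by 10.25 ± 0.58 (88.4 ± 10.8 against 0.0681 ± 0.0311 CPM). Osr2 was higher by 8.02 ± 0.79 (222 ± 2.75 against 0.855 ± 0.513 CPM). Lower in epithelium were Tcf21, a mesenchymal bHLH factor (-6.52 ± 0.30), Bmp4, a BMP ligand (-5.75 ± 0.31), and Smoc2 (-6.47 ± 0.33; 1.06 ± 0.378 against 94.7 ± 16.7 CPM). In all, 1808 genes were higher and 1670 lower of 15680. Of 38 lists 22 passed and 17 still did with an estimated correlation. All 25 tested endoderm and epithelium members were higher (adjusted p = 1.4e-89, and adjusted p = 3.6e-06 with an estimated correlation). Of 18 mesenchyme members 15 were lower and 1 higher (adjusted p = 0.0041 with an estimated correlation), and all 8 erythroid members were lower (adjusted p = 0.00024 with an estimated correlation). Cell cycle genes were lower in epithelium (0 higher, 16 lower, 12 not passing of 28; adjusted p = 0.042 with an estimated correlation), such as Mki67, a proliferation antigen (-2.15 ± 0.20). The proximal (7 of 11 higher, 0 lower) and distal (5 of 10 higher, 0 lower) lists were both higher in epithelium (adjusted p = 0.0077 and 0.0041 with an estimated correlation).

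What set Lgr5+ cells apart within the Id2KO epithelium was addressed by Id2KO Lgr5+ against EpCAM+ cells at E11.5 (n = 3 each). Lgr5 rose by 4.16 ± 0.51 (103 ± 25.5 against 5.78 ± 2.98 CPM, adjusted p = 0.0014), and Smoc2 by 2.05 ± 0.23 (1068 ± 105 against 259 ± 66.8 CPM). Of the Wnt ligand genes, Wnt11 rose by 3.88 ± 0.24 (148 ± 28.7 against 10.03 ± 2.02 CPM) and Wnt6 by 9.37 ± 1.32 (8.66 ± 3.85 against 0.0091 ± 0.0158 CPM). The inhibitor gene Sfrp5 fell by 3.46 on the log2 scale (88.4 ± 11.9 against 972 ± 175 CPM). Of the distal genes, Osr2 rose by 2.90 ± 0.28 and Cubn, a vitamin B12 receptor, by 2.92 ± 0.37. Of the proximal factor genes, Onecut2 fell by 2.79 (64.1 ± 21.9 against 442 ± 114 CPM) and Gata4 by 1.17 on the log2 scale. Vim also rose, by 2.93 ± 0.34 (630 ± 56.4 against 82.5 ± 50.5 CPM). In all, 240 genes were higher and 236 lower of 15153 tested, and 721 were called with the replicate number as a block, with 428 called in both fits.

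Leucocyte transcripts accompanied this contrast. C1qa, a complement gene of macrophages, was 120, 133 and 0.0553 CPM in the Id2KO EpCAM+ libraries and at most 0.121 in Lgr5+ libraries. In wild-type EpCAM+ libraries it ranged from 15.2 to 132 CPM. Cd79b, a B cell receptor chain, was 13.1, 13.7 and 2.9 CPM in the Id2KO EpCAM+ libraries and 0 in Lgr5+ libraries. On the group mean it was at least 114-fold lower in Lgr5+ cells. It does not mark leucocytes alone, since E13.5 EpCAM+ libraries held 2.6 to 4.77 CPM with C1qa at 0. Lists passed in 17 of 38 cases and 0 of these passed with an estimated correlation, with or without the block. Wnt ligands and inhibitors had 3 higher, 1 lower and 10 not passing of 14, with 6 and 2 over the list alone (adjusted p = 0.049, but adjusted p = 0.21 with an estimated correlation and adjusted p = 0.21 with the block). Liver genes passed only with the block (adjusted p = 0.035 against 0.14). The stem cell list had 6 higher, 0 lower and 22 not passing of 28, with 8 and 1 over the list alone (adjusted p = 6.2e-05, but adjusted p = 0.053 with an estimated correlation). The proximal list had 0 higher, 4 lower and 7 not passing of 11, with 0 and 7 over the list alone (adjusted p = 5.8e-10, but adjusted p = 0.053 with an estimated correlation). The distal list had 3 higher, 0 lower and 5 not passing of 8, with 4 and 2 over the list alone (adjusted p = 0.053 with an estimated correlation). Stress and immediate early genes had 0 higher, 6 lower and 11 not passing of 17, with 0 and 8 over the list alone (adjusted p = 0.053 with an estimated correlation). Fos, an immediate early factor, fell by 0.99 on the log2 scale. Leaving out Lgr5+ replicate 1, 2 or 3 gave 224, 261 and 259 genes, against 476.

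Against wild-type EpCAM+ cells the Id2KO Lgr5+ cells (n = 3 each) combined both differences. Id2 fell by 5.50 on the log2 scale (131 against 5915 CPM, adjusted p = 5.2e-08), Lgr5 rose by 3.83 ± 0.50 (adjusted p = 0.0022) and Smoc2 by 9.85 ± 0.33 (1068 ± 105 against 1.15 ± 0.405 CPM, adjusted p = 5e-08). Krt15, a keratin of stratified epithelia, rose by 8.63 ± 0.75 (13.01 ± 3.1 against 0.0284 ± 0.0276 CPM), and Bmp7 rose by 2.49 ± 0.17. Cyp26a1, the enzyme that degrades retinoic acid, fell by 7.25 on the log2 scale (0.0763 ± 0.132 against 12.4 ± 2.69 CPM). Osr2, low in Id2KO EpCAM+ cells, averaged 190 plain CPM in these Lgr5+ cells and 243 in wild-type EpCAM+ cells. In all, 255 genes were higher and 206 lower of 15153. Of 38 lists 14 passed and 0 still did with an estimated correlation. The closest was the stem cell list (5 higher, 0 lower, 23 not passing of 28; 8 and 1 over the list alone; adjusted p = 0.053 with an estimated correlation). Leaving out wild-type replicates 1, 2 or 3 gave 305, 189 and 203 genes, and leaving out Lgr5+ replicates 1, 2 or 3 gave 248, 237 and 198, against 461. Without the 3 EpCAM+ libraries over 100 CPM of C1qa, 810 genes were called.

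At E13.5, Lgr5+ against EpCAM+ cells (n = 4 each) addressed what sorted Lgr5+ progenitors share beyond the marker. Lgr5 rose by 1.98 ± 0.16 (90.6 ± 6.54 against 23.0 ± 1.26 CPM, adjusted p = 4.2e-05), Smoc2 by 3.80 ± 0.29 (28.4 ± 5.81 against 2.05 ± 0.511 CPM). Ascl2, a stem cell bHLH factor driven by Wnt, rose by 1.82 ± 0.26 (32.4 ± 7.0 against 9.17 ± 2.47 CPM, adjusted p = 0.0021). Id2 itself did not pass (-0.02 ± 0.17, adjusted p = 1.0; 3128 ± 414 against 3175 ± 669 CPM). The other side of the contrast was regional. Onecut2 and Gata4, transcription factors of the proximal gut, fell by 4.03 (25.9 ± 17.8 against 424 ± 90.6 CPM, adjusted p = 0.00043) and 2.88 on the log2 scale. Fabp1, a fatty acid binding protein of proximal enterocytes, fell by 3.49. Cubn rose by 1.78 ± 0.20 and Hoxb7, a posterior Hox gene, by 2.44 ± 0.41 (13.5 ± 3.88 against 2.49 ± 1.17 CPM). In all, 106 genes were higher and 128 lower of 13355 tested, with 1300 at an unadjusted p under 0.05. Leaving out any 1 library left 157 to 223 called genes, against 234.

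Of 36 lists 15 passed at E13.5 and 7 still did with an estimated correlation. Proximal small intestine had 0 higher, 6 lower and 4 not passing of 10, with 0 and 7 over the list alone (adjusted p = 1.1e-24, and adjusted p = 0.002 with an estimated correlation). Foregut and stomach had 0 higher, 3 lower and 12 not passing of 15 (adjusted p = 0.039 with an estimated correlation). Distal small intestine had 3 higher, 0 lower and 5 not passing of 8, with 5 and 0 over the list alone (adjusted p = 0.005 with an estimated correlation). Posterior Hox had 2 higher, 0 lower and 2 not passing of 4 (adjusted p = 0.039 with an estimated correlation). It was not called when no filter on low counts was used (median -0.32, adjusted p = 0.34). The stem cell list had 5 higher, 0 lower and 23 not passing of 28, with 7 and 0 over the list alone (adjusted p = 0.002 with an estimated correlation). Wnt targets had 4 higher, 0 lower and 18 not passing of 22 (adjusted p = 0.013 with an estimated correlation). Enterocyte genes split, 2 higher, 6 lower and 13 not passing of 21 (adjusted p = 0.033 with an estimated correlation). Mep1a, a brush border protease, rose by 2.11 ± 0.27, and Apoa1, an apolipoprotein, fell by 2.22 on the log2 scale. Cell cycle genes had 3 higher, 0 lower and 25 not passing of 28, with 11 and 0 over the list alone (adjusted p = 0.12 with an estimated correlation). The Lgr5+ fraction was thus higher in both stem cell and distal genes and lower in proximal genes. Vim rose here as well, by 1.92 ± 0.20 (360 ± 53.2 against 95.1 ± 27.9 CPM).

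**Figure D2:**
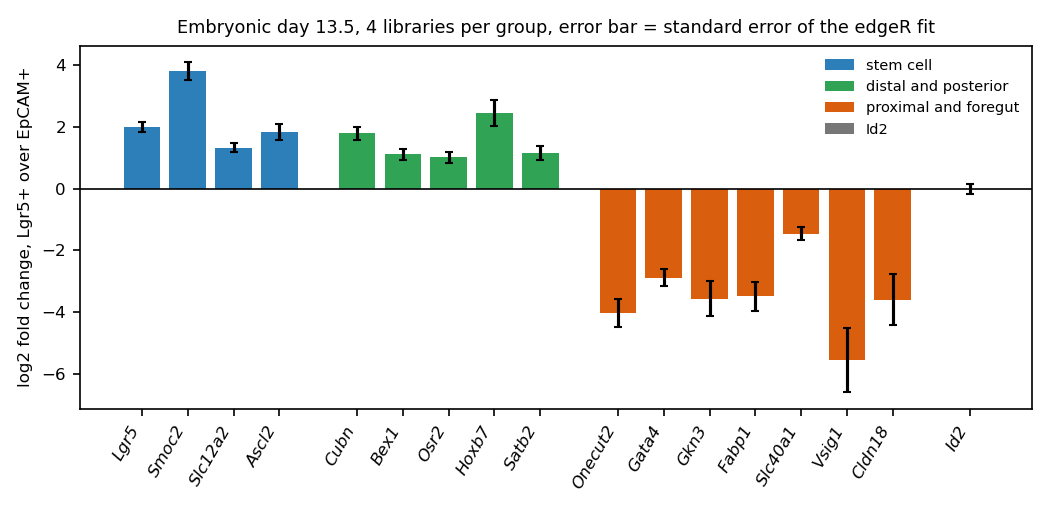
Log2 fold change of stem cell, distal and proximal genes and Id2 in E13.5 Lgr5+ against EpCAM+ cells (n = 4 each), with bars of 1 standard error. Lgr5 was at 1.98, Onecut2 at -4.03 and Id2 at -0.02.

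How much of the E13.5 contrast was already present in Id2KO embryos at E11.5 was asked by overlapping both Lgr5+ against EpCAM+ comparisons. Of 13117 genes tested in both, 30 were higher in both (1.7 by chance, Fisher p = 1.1e-29), 39 were lower in both (2.1 by chance, p = 5e-39) and 3 had opposite directions. Shared rises included Lgr5, Smoc2, Cubn and Osr2, and shared falls Onecut2, Gata4 and Gkn3, a gastrokine of stomach and proximal gut. Across all genes the Pearson correlation of the log2 fold changes was 0.22 and the Spearman correlation 0.18. Genes are not independent replicates, so no p is given for the correlations, and the Fisher p carries the same limit. The E11.5 comparison lacks a wild-type Lgr5+ group, so this overlap does not say what Id2 does to the program.

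What development changed in the epithelium was addressed by EpCAM+ cells at E13.5 (n = 4) against wild-type E11.5 (n = 3). Lgr5 rose by 1.86 ± 0.35 (24.5 ± 1.24 against 6.74 ± 3.27 CPM, adjusted p = 0.0011) while Id2 fell by 0.71 on the log2 scale (3385 ± 729 against 5533 ± 846 CPM, adjusted p = 0.01). That fall missed the threshold without wild-type replicate 3 (-0.59, adjusted p = 0.057). Wnt targets and feedback genes had 9 higher, 5 lower and 10 not passing of 24 (adjusted p = 0.024, but adjusted p = 0.28 with an estimated correlation). Lgr4, a relative of Lgr5, rose by 5.68 ± 0.29 (3530 ± 1120 against 69.1 ± 7.21 CPM). Sp5, a Wnt target factor, fell by 7.28 on the log2 scale. Id1, a BMP target, fell by 2.84 (16.3 ± 3.46 against 117 ± 25.8 CPM), and Anpep, a brush border peptidase, rose by 2.93 ± 0.21 (148 ± 6.43 against 19.3 ± 5.17 CPM). C1qa was at 0 CPM in the E13.5 libraries and at 132, 40.8 and 15.2 CPM in the E11.5 libraries. In all, 2791 genes were higher and 3055 lower of 14467. The labels give single embryos at E11.5 and pools at E13.5, but the E11.5 libraries held both Xist and Ddx3y, so whether pooling differed is unclear. Sorting day may have differed with stage. Sex mix did differ: Ddx3y was 82.1 to 158 CPM in the E13.5 and 18.0 to 25.8 CPM in the E11.5 libraries. Xist was 136 to 223 and 251 to 575 CPM in the same order. The sex-linked list had 4 higher and 1 lower of 5 (adjusted p = 0.0099, but adjusted p = 0.33 with an estimated correlation). Reads without a gene were 22.8 to 28.7% in these E13.5 libraries and 14.5 to 20.4% in the E11.5 ones. Stage was therefore not separated from sex mix or processing. Of 38 lists 9 passed and 0 still did with an estimated correlation. The enterocyte list (12 higher, 3 lower, 6 not passing of 21) and BMP signalling (1 higher, 9 lower, 4 not passing of 14) both had adjusted p = 0.18 with an estimated correlation.

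Whether loss of Id2 at E11.5 moved the epithelium toward its later state was asked by overlapping the genotype and stage effects. Of 14219 genes tested in both, 50 were higher in both (24.1 by chance, Fisher p = 7.2e-08), 72 were lower in both (25.6 by chance, p = 2.6e-20), and 31 and 13 had opposite directions (27.1 and 22.7 by chance). Both comparisons used the same wild-type libraries, which by itself creates a positive correlation. The observed covariance across genes was 0.474 and the simulated one from shared controls alone 0.256 to 0.291 (mean 0.275) in 20 simulations. The Pearson correlation was 0.26 observed and 0.53 simulated, but the observed one is scaled by the large changes with stage, which the simulation left out. The covariance therefore exceeded what simulated scatter of shared controls gave. The simulation drew each gene independently around the wild-type mean. It did not cover features that the shared wild-type libraries held alike, such as their sex mix or other cells in the sort. Such features could also raise the covariance, so a move toward the later state was not shown. The same simulations gave 0 shared calls, but without any change in either group few calls of any kind are expected. The Fisher tests treat genes as independent and do not allow for the shared controls, so how far sharing added to the real shared calls was left open.

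Adult Lgr5+ stem cells against E13.5 Lgr5+ cells (n = 4 each) addressed what separates a fetal from an adult Lgr5+ cell. Id2 fell by 3.27 on the log2 scale (313 ± 91.9 against 3033 ± 411 CPM, adjusted p = 3.3e-07) as Lgr5 rose by 2.19 ± 0.18 (400 ± 91.3 against 87.8 ± 6.7 CPM, adjusted p = 1.8e-06). Olfm4, a secreted marker of adult stem cells, rose by 10.46 ± 0.33 (5479 ± 482 against 3.87 ± 1.41 CPM), Smoc2 by 3.57 ± 0.19 and Axin2, a Wnt feedback gene, by 4.10 ± 0.23. Cd74, the MHC class II invariant chain, rose by 11.41 ± 0.44 (8306 ± 3480 against 3.04 ± 0.573 CPM). Fetal growth genes fell. Igf2, a growth factor, fell by 8.28 on the log2 scale (1.22 ± 0.314 against 379 ± 93.5 CPM), and Igf2bp1, an oncofetal RNA-binding protein, went from 143 ± 9.47 to 0.39 ± 0.112 CPM. In all, 2450 genes were higher and 2274 lower of 13144.

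Of 35 lists 20 passed in the adult to E13.5 comparison and 10 still did with an estimated correlation. Stem cell genes had 19 higher, 1 lower and 8 not passing of 28, Paneth genes 16 higher and 1 lower of 17, oncofetal RNA-binding genes 8 of 8 lower, and imprinted growth genes 11 of 12 lower and 0 higher (each adjusted p = 0.00088 with an estimated correlation). MHC class II had 7 of 7 higher (adjusted p = 0.035 with an estimated correlation) and the interleukin-22 responsive list 8 of 10 higher and 0 lower (adjusted p = 0.025 with an estimated correlation). Pigr, the immunoglobulin transporter, rose by 10.33 ± 0.27. Wnt targets had 11 higher, 2 lower and 9 not passing of 22 (adjusted p = 0.049 with an estimated correlation). Hedgehog had 0 higher, 3 lower and 4 not passing of 7 (adjusted p = 0.028 with an estimated correlation), with Shh down (-9.30 ± 0.53). Cell cycle genes had 0 higher, 13 lower and 15 not passing of 28 (adjusted p = 0.082 with an estimated correlation). Age and sex mix differed together here, and sorting day may have differed with them. Lyz1, a Paneth cell lysozyme, was 76.0 ± 26.0 CPM in the adult libraries.

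The adult segment libraries addressed whether Id2 matters after birth, but Id2 was not lower in the libraries labelled Id2KO. It was higher in the anterior segment (1.23 ± 0.19, adjusted p = 0.0053; 197 ± 0.124 against 84.0 ± 26.1 CPM) and did not pass in the middle (-0.13 ± 0.19, adjusted p = 0.78). In the posterior segment it was higher (0.87 ± 0.19, adjusted p = 0.02; 148 ± 20.2 against 81.0 ± 7.01 CPM). That call was lost without Id2KO replicate 1 or 2 (1.01, adjusted p = 0.056, and 0.73, adjusted p = 0.11) or wild-type replicate 1 or 2 (0.79, adjusted p = 0.13, and 0.96, adjusted p = 0.083). Exon-level reads were not available, so a deletion that leaves transcripts counted under Id2 was not excluded. Wild-type segment libraries themselves held only 64.1 to 125 plain CPM of Id2. The E11.5 Id2KO libraries still held 108 to 182 plain CPM. At such levels the lack of a fall does not show that Id2 was intact. Lgr5 was not called in any segment (-0.88 ± 0.28, 0.03 and -0.32).

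In the anterior segment (n = 2 each) the libraries labelled Id2KO had lower MHC class II and higher interferon transcripts. H2-Ab1, an MHC class II chain, fell by 3.93 on the log2 scale (4.19 ± 1.95 against 64.6 ± 3.16 CPM, adjusted p = 0.0023). Irf7, an interferon regulatory factor, rose by 2.13 ± 0.25 (59.4 ± 13.2 against 13.5 ± 3.09 CPM, adjusted p = 0.00076). Ung, a uracil DNA glycosylase, rose by 3.59 ± 0.27 (93.9 ± 7.81 against 7.79 ± 1.84 CPM). Cyp2e1, an ethanol-metabolising enzyme, fell by 4.15 on the log2 scale (6.67 ± 2.33 against 118 ± 11.4 CPM). Rpl3, a ribosomal protein gene with pseudogenes, fell by 4.34 (6.08 ± 0.897 against 124 ± 4.85 CPM). In all, 108 genes were higher and 94 lower of 13436. Of 35 lists 6 passed and 3 still did with an estimated correlation. These were MHC class II (0 higher, 5 lower, 3 not passing of 8; 0 and 7 over the list alone; adjusted p = 0.011) and interferon response (5 higher, 0 lower, 14 not passing of 19; 7 and 0 over the list alone; adjusted p = 0.039). The last was fetal spheroid genes (2 higher, 0 lower, 10 not passing of 12; 6 and 0 over the list alone; adjusted p = 0.011). Leaving out wild-type replicate 1 or 2 gave 360 and 73 genes, and Id2KO replicate 1 or 2 gave 86 and 125, against 202. Wild-type replicate 1 held 29.1 CPM of Gzma, a T cell granzyme.

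In the posterior segment (n = 2 each) MHC class II genes fell as well. Cd74 fell by 8.51 on the log2 scale (5.96 ± 1.14 against 2184 ± 199 CPM, adjusted p = 0.00035) and H2-Ab1 by 8.16 (2.27 ± 0.57 against 643 ± 155 CPM, adjusted p = 3.9e-05). Hspa1b, an inducible heat shock protein, rose by 1.65 ± 0.19 and Egr1, an immediate early factor, by 0.87 ± 0.13 (1241 ± 74.8 against 678 ± 86.0 CPM). Dio1, a thyroid hormone deiodinase, rose by 6.74 ± 0.96 (38.7 ± 0.0197 against 0.348 ± 0.281 CPM). Cyp2e1 fell by 10.14 on the log2 scale. In all, 343 genes were higher and 350 lower of 13436. Of 35 lists 15 passed and 3 still did with an estimated correlation. MHC class II had 8 of 8 lower (adjusted p = 4.2e-54, and adjusted p = 0.0032 with an estimated correlation). The others were stress and immediate early (12 higher, 0 lower, 5 not passing of 17; 14 and 1 over the list alone; adjusted p = 0.041) and fetal spheroid (4 higher, 0 lower, 8 not passing of 12; adjusted p = 0.041). Region lists also moved, distal with 3 higher, 0 lower and 11 not passing of 14 and proximal with 0 higher, 3 lower and 11 not passing of 14 (both adjusted p = 0.31 with an estimated correlation). On the mean of middle and posterior segments the distal median turned (-1.24 against 0.99) and the proximal list did not pass (adjusted p = 0.9; median -0.26). Bex1, a distal list member, rose by 2.68 ± 0.27, but its sign turned on that mean (-1.20). Leaving out Id2KO replicate 1 gave 182 genes and wild-type replicate 1 or 2 gave 270 and 276, against 693.

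The middle segment (n = 2 each) showed the opposite regional shift. Bex1 fell by 5.08 on the log2 scale (2.91 ± 0.234 against 98.9 ± 12.6 CPM, adjusted p = 1.9e-06) and Gata4 rose by 3.30 ± 0.37 (147 ± 27.2 against 14.9 ± 10.2 CPM, adjusted p = 0.00036). H2-Ab1 fell by 5.53 (9.61 ± 5.81 against 446 ± 8.48 CPM, adjusted p = 0.0002), and Hspa1a, a heat shock protein, rose by 4.19 ± 0.36. In all, 219 genes were higher and 307 lower of 13436. Of 35 lists 10 passed and 5 still did with an estimated correlation. Among them were MHC class II (0 higher, 6 lower, 2 not passing of 8; 0 and 8 over the list alone; adjusted p = 0.0052) and distal small intestine (0 higher, 6 lower, 8 not passing of 14; 0 and 7 over the list alone; adjusted p = 0.021). Posterior Hox had 0 higher, 3 lower and 2 not passing of 5 (adjusted p = 0.0052). Leaving out Id2KO replicate 1 or 2 gave 257 and 171 genes, and wild-type replicate 1 or 2 gave 235 and 194, against 526. Ileal transcripts in the wild-type libraries were the reverse of the labels' order. Fabp6, the ileal bile acid binding protein, was 630 and 238 CPM in wild-type middle and 0.294 and 0.472 CPM in wild-type posterior libraries. The regional part of both comparisons rests on the segment labels.

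**Figure D3:**
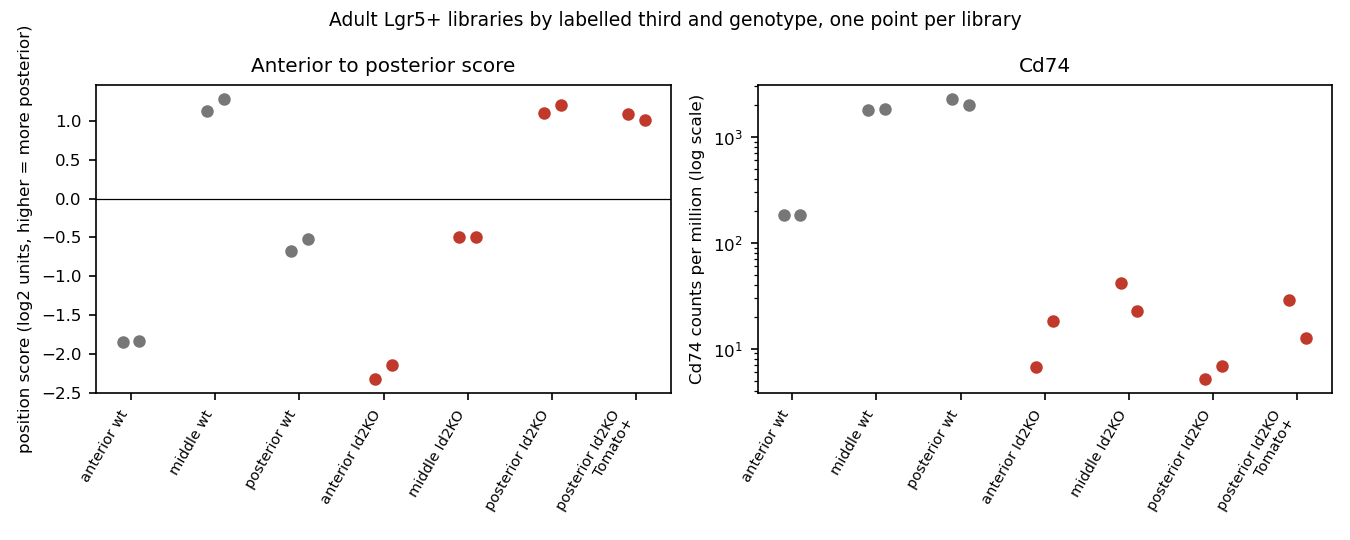
Left, position score of each adult segment library, as the mean difference between posterior and anterior genes; right, Cd74 in plain CPM on a log scale; n = 2 per group. Wild-type middle libraries scored 1.13 and 1.29 and wild-type posterior libraries -0.68 and -0.52; mean Cd74 was 2159 CPM in wild-type posterior and 5.97 in posterior cells labelled Id2KO.

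Regional identity within each genotype label was addressed by anterior against posterior cells (n = 2 each). In the libraries labelled Id2KO, Bex1 fell by 6.45 on the log2 scale (0.578 ± 0.238 against 52.0 ± 0.67 CPM, adjusted p = 1.1e-06) and Osr2 by 4.87 (12.6 ± 5.67 against 369 ± 43.6 CPM). Gkn3 rose by 2.74 ± 0.24, and Pdx1, the duodenal homeobox gene, was at least 171-fold higher in anterior cells. There, 130 genes were higher and 139 lower of 13436. Of 35 lists 9 passed and 4 still did, each with adjusted p = 0.023 with an estimated correlation. These were distal (0 higher, 4 lower, 10 not passing of 14), proximal (4 higher, 0 lower, 10 not passing of 14), foregut (4 higher, 0 lower, 6 not passing of 10) and posterior Hox (0 higher, 2 lower, 3 not passing of 5). Wild-type cells gave 407 higher and 239 lower, with Osr2 down (-2.11 ± 0.25, adjusted p = 0.0018). H2-Eb1, an MHC class II chain, was also down (-3.40 ± 0.31, adjusted p = 0.00039; 13.5 ± 1.95 against 143 ± 41.1 CPM). Of 35 lists 7 passed there and 0 still did. MHC class II had 0 higher, 6 lower and 2 not passing of 8 (adjusted p = 0.052 with an estimated correlation). The distal list, called lower, had a median of -0.28 but a mean of 0.12 (adjusted p = 0.49 with an estimated correlation). Leaving out anterior wild-type replicate 1 or 2 gave 1405 and 27 genes and posterior wild-type replicate 1 or 2 gave 157 and 96, against 646. In the Id2KO comparison, leaving out anterior replicate 2 gave 138 genes and posterior replicate 1 or 2 gave 124 and 139, against 269.

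Whether the effect of the Id2KO label differed between segments was tested as posterior minus anterior (n = 2 in each of 4 groups). Bex1 (3.88 ± 0.46, adjusted p = 0.0051) and Osr2 (2.76 ± 0.35, adjusted p = 0.0062) had positive terms, both distal genes and so both open to the order of the wild-type segments. Terms were positive for 20 genes and negative for 23 of 13436, with 2010 at an unadjusted p under 0.05. Of 35 lists 9 passed and 0 still did with an estimated correlation. MHC class II had 0 higher, 2 lower and 6 not passing of 8, with 0 and 7 over the list alone (adjusted p = 0.078 with an estimated correlation). Leaving out 1 library at a time moved the count to 66 and 18 (anterior Id2KO replicates 1 and 2), 262 and 11 (anterior wild-type 1 and 2), 6 (posterior Id2KO 1) and 13 and 28 (posterior wild-type 1 and 2), against 43.

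What the anterior and posterior effects had in common was asked by their overlap. Of 13436 genes, 57 were higher in both (2.8 by chance, Fisher p = 9.2e-63), 49 were lower in both (2.4 by chance, p = 4.2e-53) and 3 had opposite directions. Cyp2e1, H2-Ab1 and H2-Eb1 were among the shared falls and Dio1 and Hspa1b among the shared rises. Across genes the Pearson correlation was 0.20 and the Spearman correlation 0.12. Each genotype label had 2 animals or pools per segment, so the overlap measured a difference between those animals as well as any effect of genotype. The Fisher p treats genes as independent and does not measure spread between animals.

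Tomato+ against Lgr5+ posterior cells labelled Id2KO (n = 2 each) addressed whether lineage-labelled cells differ from the sorted stem cells. edgeR called 0 of 13436 genes, with 358 at an unadjusted p under 0.05, DESeq2 called 1 and the fit without a filter on low counts 66. Lgr5 (0.06, adjusted p = 1; 271 against 260 CPM) and Id2 (-0.25, adjusted p = 1) did not pass. Of 35 lists 5 passed and posterior Hox still did with an estimated correlation (0 higher, 0 lower, 5 not passing of 5; 0 and 3 over the list alone; adjusted p = 4.8e-14, and adjusted p = 0.0028 with an estimated correlation). The genes were low, with Hoxb7 at 0.058 CPM in Tomato+ and 2.10 in Lgr5+ cells.

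**Figure D4:**
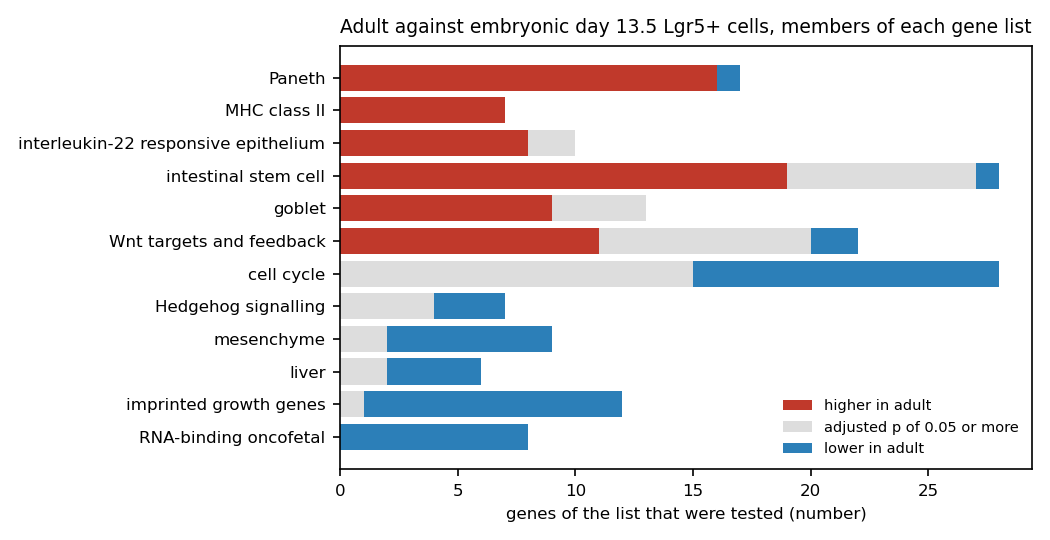
Members of 12 gene lists higher, lower or with an adjusted p of 0.05 or more, in adult against E13.5 Lgr5+ cells (n = 4 each); the axis counts genes. Of 28 stem cell genes 19 were higher and 1 was lower, and 8 of 8 oncofetal RNA-binding genes were lower.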

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

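Tests of the region score were written before its values were seen; tests of MHC class II and of other splits were chosen only after the results were seen.

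Within groups of 4 libraries, 98 sets of values were tested for a library standing far from the others, and 9 stood out, where chance alone gives about 1 in 20. All values are CPM after TMM scaling unless stated. Among E13.5 Lgr5+ libraries, Lgr5 was 80.8 CPM in replicate 2 (others 93.2 to 94.4; in plain CPM 83.6, others 89.5 to 94.7, so the gap depends on the scaling), Apcs 2.68 in replicate 2 (others 0.101 to 0.296), Vsig1 0.8288 in replicate 4 (others up to 0.101), and Glod5 and Iigp1 were each 0.0288 in replicate 4 (others 0). Among adult stem cell libraries, Sis, an enterocyte disaccharidase, was 238 CPM in replicate 4 (others 7.67 to 9.36), Lrch2 0.0703 in replicate 4, Gjc1 0.107 in replicate 1 and Kcnk2 0 in replicate 1 (others 0.0319 to 0.0364). The values of Glod5, Iigp1, Lrch2, Gjc1 and Kcnk2 rest on 0 to 3 reads per library, so they carry no weight.

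The effect of Id2KO differed between E11.5 EpCAM+ cells and mesenchyme for 93 genes by the interaction term. Among the positive terms (EpCAM+ minus mesenchyme) were Necab1 (16.88), Krt15 (10.95), Wdr65 (7.90), Smoc2 (7.02), Enpp3 (6.53), Cxcl16 (5.31) and Gpx2 (4.30). Negative terms, which can also come from a larger fall in EpCAM+ cells, included Wt1 (-6.72), Dbc1 (-5.75), Emilin3 (-5.49), Penk (-5.37), Esr1 (-4.59), Ddr2 (-4.55), Col5a2 (-4.55) and Col11a1 (-4.47). Vim was 207, 192 and 180 CPM in wild-type and 60.5, 143 and 43.1 CPM in Id2KO EpCAM+ libraries. Vim does not measure mesenchyme alone, being at 571 to 688 CPM in Id2KO Lgr5+ and 215 to 430 CPM in mesenchyme libraries. Col3a1, of the mesenchyme list, was 4.57 to 9.3 CPM in wild-type and 0.743 to 2.65 CPM in Id2KO EpCAM+ libraries. In mesenchyme libraries it was 376 to 824 CPM. Negative terms of mesenchymal genes were thus not separated from mesenchyme carried over in the wild-type sort. The value for Necab1, with a group at 0, depends on the prior count. Of 100 drawn splits of the 12 libraries, 1, the real one, gave as many genes (highest other 51). The splits exchanged genotype labels within each tissue, which also breaks up effects that both tissues share. They therefore cannot decide whether a difference between the tissues arose by chance.

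The effect of the Id2KO label differed between adult posterior and anterior cells for 43 genes by the interaction term. Positive terms (posterior minus anterior) included Ppp4r4 (4.04), Bex1 (3.88), Naaladl1 (3.86), Osr2 (2.76), Plch2 (2.43), Samd4b (2.14), Abat (2.01) and Abcb1a (1.77). Negative terms, which for H2-Ab1 and Cyp2e1 come from a larger posterior fall (-8.16 against -3.93 and -10.14 against -4.15), included Crp (-11.07, with a group at 0, so dependent on the prior count), Cyp2e1 (-5.99), Efcab1 (-4.87), H2-Ab1 (-4.23), H2-Eb1 (-3.27), Pgc (-3.09), Adh1 (-2.75) and Gkn3 (-2.54). With 2 libraries per group no splits were counted.

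The regional genes in that list depend on which wild-type libraries were posterior. On a score of 132 posterior and 124 anterior genes, called between Id2KO segments and outside the region lists, the lowest wild-type middle library lay 1.66 above the highest wild-type posterior library, and an exchange of the wild-type middle and posterior labels is a candidate explanation. Segments taken at other positions in the wild-type animals would shift the scores but keep their order, and 4 of the 4 pairs of a middle and a posterior library had the middle one more posterior. A reversed order of distal and proximal cells in those animals was not tested as biology. Labels were left as given, and comparisons that name wild-type middle or posterior cells carry this doubt.

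MHC class II genes fell in all segments of the libraries labelled Id2KO, while Id2 itself, already low in the wild-type segments, was not lower. Leucocytes in the wild-type libraries would bring their other transcripts, but the summed leucocyte list reached at most 2.97% of the Cd74 level in the 4 wild-type middle and posterior libraries; in the anterior ones it reached 59.6%, so leucocytes stay open there. What stays open is a difference between the animals other than Id2, such as housing, microbiota or background, which could alter the same genes in every segment: 55 genes were called in the same direction in all 3 segments, and genotype and animals cannot be told apart with the libraries at hand. A role of Id2 in MHC class II expression is a hypothesis that these libraries leave untested.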

How the results depend on the processing

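The settings fixed beforehand were the size factors, the test, the filter, the block, the groups fitted and the libraries left out; the covariate, the segment means, the C1qa limit and the crossed numbers were chosen only after the results were seen. RLE size factors moved none of the 19 counts by over 1.5 times. Of the values for named genes, 929 stayed the same in call and direction with RLE and 2 lost a call; with DESeq2 these were 922 and 9. With the correlation estimated, 55 of the list calls stood and 127 were lost; with fry, 137 and 45. Leaving out 1 library at a time left 4677 gene values the same, ended the call of 1130 and turned the sign of 13; for lists these were 1028, 116 and 1. Where this left 1 library in an adult group, that library was assumed to vary like the others. The cause of these shifts was not tested.

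The DESeq2 Wald test called over 1.5 times as many genes as edgeR in 16 of the 19 counts. At E11.5 it gave 727 for EpCAM+ Id2KO against wild-type, 293 for mesenchyme, 315 for their interaction, 1146 for Id2KO Lgr5+ against EpCAM+ and 1243 for Id2KO Lgr5+ against wild-type EpCAM+, and 466 for Lgr5+ against EpCAM+ at E13.5. In adults it gave 570 (anterior), 1132 (middle), 1343 (posterior), 537 (interaction), 1549 (wild-type anterior against posterior), 544 (the same in Id2KO) and 1 (Tomato+). Shared genes in the 3 overlaps became 330, 150 and 219, in the order of the report's genotype with stage, Lgr5+ at both stages and adult anterior with posterior.

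Without a filter on low counts, adult counts rose to 766, 1302 and 1447 (anterior, middle, posterior), 868 (interaction), 1654 and 675 (anterior against posterior in wild-type and Id2KO), 66 (Tomato+) and 283 (adult overlap). Fitting the compared groups alone gave 119 (E11.5 EpCAM+ Id2KO), 972 (Id2KO Lgr5+ against wild-type), 44 (adult anterior), 340 (middle), 25 (interaction) and 47 (wild-type anterior against posterior).

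The replicate number as a block gave 721 genes for Id2KO Lgr5+ against EpCAM+, where the numbers paired the libraries, and moved none of the other 18 counts by over 1.5 times. In that comparison it ended the calls of Cela1 (-1.71, adjusted p = 0.076), Dlk1 (-2.33, adjusted p = 0.064) and the Wnt ligand list, brought in the liver list, and ended no other call among the named genes and lists. Elsewhere the pairing rule was not met: same-numbered correlations were 0.10, -0.02 and 0.22 for E11.5 EpCAM+ Id2KO and wild-type, and 0.01, 0.18, 0.03 and 0.05 at E13.5, and not every library correlated best with its own number. Adult Id2KO anterior and posterior libraries correlated at 0.15 with the same number and -0.15 with the other, which 2 libraries per group make equal and opposite. Replicate 1 of the Id2KO EpCAM+, Lgr5+ and mesenchyme libraries was rich in Xist (874, 735 and 318 CPM) and replicates 2 and 3 in Ddx3y, a hint from the data that a number marks an embryo across these groups; the labels do not say so. For the pair of 2-library groups with a correlation of -0.10, Tomato+ and Lgr5+, a block with crossed numbers also gave 0 genes.

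Left-out libraries moved the E11.5 counts over 75 to 301 (EpCAM+ Id2KO), 67 to 129 (mesenchyme), 67 to 142 (interaction), 224 to 557 (Id2KO Lgr5+ against EpCAM+) and 189 to 305 (against wild-type). Adult ranges were 73 to 360 (anterior), 171 to 257 (middle), 182 to 504 (posterior), 6 to 262 (interaction), 27 to 1405 (wild-type anterior against posterior), 124 to 198 (the same in Id2KO) and 0 to 1 (Tomato+, edgeR). Gene signs turned only for values that were not called. Lgr5 ranged from -0.66 to 0.05 in EpCAM+ Id2KO, from -2.33 to 0.94 in the E11.5 interaction, from -0.13 to 0.18 in the adult middle segment, from -0.36 to 0.41 between wild-type segments and from -0.09 to 0.23 in Tomato+ cells. Id2 ranged from -0.16 to 0.07 at E13.5, from -0.29 to 0.05 in the middle segment and from -0.30 to 0.34 between wild-type segments. The median of the goblet list between Id2KO segments ranged from -2.34 to -0.09, and the direction of its test turned without anterior Id2KO replicate 2.

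Leaving out the 3 EpCAM+ libraries with over 100 CPM of C1qa gave 810 genes for Id2KO Lgr5+ against wild-type EpCAM+ and turned Lgr5 in EpCAM+ Id2KO (0.47, not called); the other counts were 171 (EpCAM+ Id2KO), 386 (Lgr5+ against EpCAM+) and 4832 (stage). The Hbb-y covariate in mesenchyme nearly repeats the genotype (correlation -0.94), so a loss of calls was expected from the design and says nothing about stability. It left 1 gene called, Esr1 (8.60 ± 0.84 against 8.83 ± 0.41). Id2 was -4.22 ± 0.47 against -4.52 ± 0.21 and missed the threshold because the standard error grew (adjusted p = 0.052), and Csf2rb turned (0.46). With the mean of Id2KO EpCAM+ and Lgr5+ cells in place of EpCAM+ alone, Lgr5 became 1.75.

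The mean of the middle and posterior segments, which does not depend on which of them is which, gave 1140 genes in place of both the middle and the posterior count. Against the middle comparison it turned Id2 (0.37), Lgr5 (-0.14), Crp (-2.39), Pgc (-0.50), Krt4 (1.5), Duoxa2 (0.14) and the stratified list (0.32). Against the posterior comparison it turned Gkn3 (1.27), Gata4 (0.94), Bex1 (-1.20), Bex4 (-1.52), Hoxb9 (-1.32) and the distal (-1.24) and posterior Hox (-2.71) lists; the proximal list kept a median under 0 (-0.26) while the direction of its test turned (adjusted p = 0.9). Wild-type anterior cells against the mean of wild-type middle and posterior cells gave 1202 genes and turned Id2 (-0.19).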

Other observations

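Tests of the distal genes and of other splits were chosen only after the results were seen.

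The E11.5 wild-type epithelium already held transcripts of differentiated gut and liver against mesenchyme (n = 3 each). Enterocyte genes had 16 of 20 higher and 0 lower (adjusted p = 0.00075 with an estimated correlation). Liver genes had 5 of 8 higher and 0 lower (adjusted p = 0.00041 with an estimated correlation), with Afp, the fetal serum protein, higher by 9.21. In the anterior Hox, BMP signalling and Wnt ligand lists, more members were lower than higher in epithelium. Anterior Hox had 12 of 16 lower and 0 higher in epithelium (adjusted p = 0.0077 with an estimated correlation; Hoxb5 -5.28 ± 0.45), BMP signalling 4 higher, 10 lower and 4 not passing of 18 (adjusted p = 0.026 with an estimated correlation), and Wnt ligands and inhibitors 1 higher, 7 lower and 6 not passing of 14 (adjusted p = 0.038 with an estimated correlation). Smooth muscle had 9 of 10 lower (adjusted p = 0.021 with an estimated correlation), with Acta2, smooth muscle actin, at 4.28 ± 1.66 against 440 ± 147 CPM.

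Mesenchyme list genes expressed by fetal Lgr5+ cells were low in adult stem cells. In adult against E13.5 Lgr5+ cells (n = 4 each), 7 of 9 tested members were lower and 0 higher (adjusted p = 0.019 with an estimated correlation), with Vim at 0.844 ± 0.541 against 349 ± 50.0 CPM. Liver genes had 4 of 6 lower and 0 higher (adjusted p = 0.019 with an estimated correlation). Stress and immediate early genes had 11 higher, 0 lower and 6 not passing of 17, but adjusted p = 0.36 with an estimated correlation.

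Osr2 and Bex4, distal small intestine genes, fell in E11.5 Id2KO EpCAM+ cells. More mesenchyme in the wild-type epithelium is excluded, since these genes were higher in epithelium than in mesenchyme by a median of 5.91. More Lgr5+ cells among wild-type EpCAM+ cells would add Osr2, which was high in Lgr5+ cells. However, Osr2 was 231 to 255 plain CPM in wild-type EpCAM+ and 155 to 225 in Id2KO Lgr5+ libraries. For Bex4 the ranges were 405 to 507 and 257 to 363, and for Lgr5 3.31 to 10.9 and 73.8 to 119. These values argue against Lgr5+ cells as the main account of either fall. There was no wild-type Lgr5+ group at E11.5, so this holds if its levels were similar. With Lgr5 at -0.32, too uncertain to decide, a smaller part was left open. Id2KO gut pieces taken from further anterior may account for the falls. Posterior Hox genes in mesenchyme of the same stage and genotype had a median of 0.49, which neither shows nor excludes this. In EpCAM+ cells the posterior Hox list had a median of -2.38, with 0 higher, 1 lower and 6 not passing of 7. Its adjusted p was 0.042 by camera, but 0.33 with an estimated correlation. That fall does not part an anterior piece from an effect within the epithelium. An anterior piece, a smaller part from Lgr5+ cells and a direct effect of Id2 cannot be told apart here.

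Other splits of the same libraries into groups of the same sizes gave fewer genes. In the 3 comparisons with 4 libraries in at least 1 group, only 1 of 35 splits, the real one, reached its count. The counts were 234 genes for Lgr5+ against EpCAM+ at E13.5 (highest other 0), 5846 for stage (highest other 6) and 4724 for adult against E13.5 (highest other 0). A share of 1 in 35 is the smallest that these splits can give and does not exclude chance. Every other split mixes the compared groups, which adds their difference to the scatter, so low counts are likely there. The splits also cannot part a group difference from one in sex mix or processing. With 3 against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts were 251 and 1 (EpCAM+ Id2KO), 121 and 2 (mesenchyme), 3478 and 0 (EpCAM+ against mesenchyme), 476 and 0 (Id2KO Lgr5+ against EpCAM+) and 461 and 0 (Id2KO Lgr5+ against wild-type EpCAM+).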
